A study of Homo sapiens with 6 samples.

How the data were processed

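HaCaT cells were compared with and without interleukin-22 (IL-22) on Illumina HT-12 bead arrays, a 1-colour platform on which biotin-labelled copies of the cells' RNA bind to beads that carry probe sequences. Growth medium held 1.5 mM calcium and 10% serum, and the IL-22 samples received 200 ng/ml for 12 h, per the labels. There were 3 control arrays and 3 IL-22 arrays, each assigned to its group by its own title. Nothing in the labels says that arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which can be technical.

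One table with 47230 probes and 6 columns was analysed. The authors' values are on a log2 intensity scale, as deposited: this was read from their range of 7.01 to 15.4, since no header or label names the scale. GenomeStudio 2010.1 is named in the submitters' processing notes. The sorted values of the 6 arrays differed by at most 0.000461 at any rank, so the deposited log2 values had already been quantile-normalized across all 6 arrays together. Quantile normalization gives every array the same distribution, so a shift of all transcripts in 1 direction cannot be seen in these values. Background correction, variance stabilization and any probe filter are not given in the sources used here. The median of every array was 7.37 and the 75th percentile was 7.75, so most probes lay within a narrow range near the lowest values. Fold changes of such dim probes are understated if background was left in. Detection p-values, raw intensities, and slide or scan records were not used here. The precision of each value is limited by the number of arrays.

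The rows carry Illumina probe identifiers. Neither the table nor the gene table used here (GRCh38.p14 RefSeq genes) pairs these identifiers with genes, so no probe was named as a gene and no genomic position is given. The 23 gene lists written before the data were examined (filaggrin and its processing enzymes, cornified envelope, antimicrobial proteins, STAT3 targets, keratins, cytokines, markers of other cell types and others) were therefore not analysed here, and neither was filaggrin itself. The rule for named genes, also written beforehand, took the 15 largest rises and the 15 largest falls past the threshold among genes whose groups did not overlap and whose higher group lay above the median probe. It further took every filaggrin-processing gene, list members past the threshold and 4 genes of the IL-22 receptor pathway. Without gene names, only the 2 probes with the largest rise and the 2 with the largest fall under that rule are given by identifier.

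The values were used as deposited, with no further normalization. limma 3.58.1 in R 4.3.3 was fitted to all 47230 probes with group as the only term (lmFit and eBayes), with 2-sided tests and Benjamini-Hochberg adjustment over all probes. A probe was called at an adjusted p under 0.05, and a second count required a change of at least 1.5-fold. Data were simulated with the means and spread of these 47230 probes, and changes were put only into probes with a mean level above 8. The same fit called 6% of those changed 1.25-fold, 38% of those changed 1.5-fold, 84% of those changed 2-fold and 92% of those changed 3-fold (50 probes each). It called 7 of the 47030 unchanged probes. Simulated values were independent and normal, with 1 spread for both groups. In the data the median SD of probes above 8 was 0.15 in control and 0.08 with IL-22. These rates therefore do not cover dimmer probes or groups of unequal spread. Only 200 probes were changed in the simulation, while 3990 were called in the data. The adjustment is stricter when fewer probes change, so the rates can understate those in the data.

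The choices of test, threshold and most alternatives were made before the data were examined. Alternatives were cyclic loess, leaving out probes under the median level, a trended and robust variance, array weights, the replicate number as a block, an unmoderated test per probe with unequal variances, an adjusted p under 0.01, and leaving out each array in turn. Chosen after the data were examined were a background-subtracted scale (the 5th percentile of all values subtracted on the linear scale, 16 added, log2 taken again), calls from 2 arrays per group checked in the pair left out, the bands of probe level, and the level of 8 above which probes are called bright. Principal components and spreads between arrays were computed over the 9910 bright probes, whose mean over all 6 arrays was above 8. The spread between 2 arrays is the scaled median absolute deviation of their log2 differences. Figures were drawn with matplotlib 3.10.9.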

Results

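Transcript levels were measured in HaCaT cells, a spontaneously immortalized line of human epidermal keratinocytes, with and without exposure to IL-22 at 200 ng/ml for 12 h. IL-22 is a cytokine of the IL-10 family that is made by lymphocytes and acts on epithelial cells through the receptor chains IL22RA1 and IL10RB. The data comprised 3 control arrays and 3 IL-22 arrays, each with 47230 probes. All 6 arrays shared the same median of 7.37 and the same 75th percentile of 7.75 on the log2 intensity scale. A single comparison follows from the design, IL-22 against control. The series was named for filaggrin, the protein that binds keratin filaments in the upper epidermis, and for the enzymes that process its precursor. Probe identifiers were not paired with genes in the tables used here, so filaggrin and these enzymes were not analysed here and the response is described by probe.

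With IL-22, 3990 of the 47230 probes (8.45%) differed from control at an adjusted p under 0.05 (limma, Benjamini-Hochberg over all probes, n = 3 per group). Of these, 2035 rose and 1955 fell. At a change of at least 1.5-fold, 1127 probes were called, of which 417 rose and 710 fell. At least 2-fold changes were fewer, with 41 probes that rose and 163 that fell. The median absolute change of all called probes was 0.45 on the log2 scale, and the median over all 47230 probes was 0.00. Among the probes changed at least 1.5-fold, those that rose had a median change of 0.70 and those that fell a median change of -0.79 (log2). An unmoderated test per probe called 0 probes. The count in the limma fit depended on single arrays. Without control 3, 6833 probes were called, of which 1768 changed at least 1.5-fold. Without control 2 the count was 2273, and without IL-22 array 1, 2 or 3 it was 2054, 2020 and 1971.

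The split between rises and falls moved with the scaling, the variance model and the arrays used. Among all calls, 1791 probes rose and 2103 fell with a trended and robust variance, and 2549 rose and 2644 fell with array weights. With cyclic loess applied to the deposited values, 1601 called probes rose and 2240 fell. At 1.5-fold or more, 291 probes rose and 868 fell after cyclic loess, so that 25.1% rose, against 37.0% in the values as deposited. Without control 1 the split at that fold was 484 that rose and 551 that fell, or 46.8% that rose. On a background-subtracted scale 752 probes were called, of which 242 rose and 510 fell, and all of them changed at least 1.5-fold. The share that rose was thus 32.2%, against the same 37.0% in the values as deposited.

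**Figure D1:**
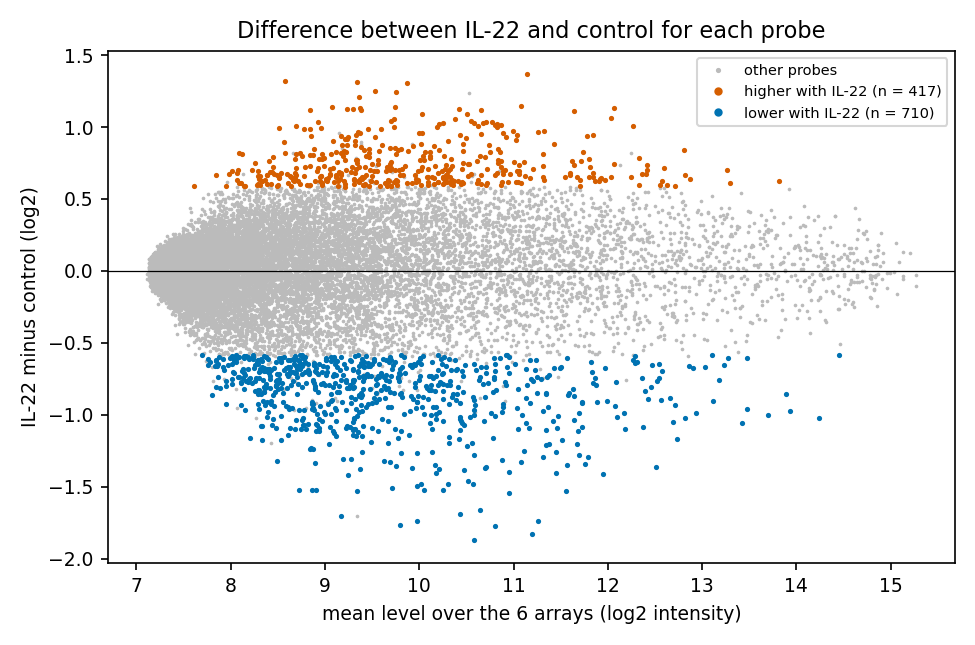
Difference between the IL-22 and control means (log2, y axis) against the mean level over the 6 arrays (log2 intensity, x axis), 1 point per probe. Coloured points passed the threshold and changed at least 1.5-fold; 417 rose and 710 fell, and the largest falls reached further from 0 than the largest rises.

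In the fit to all arrays as deposited, probe ILMN_1787879 rose most, from 10.5 ± 0.20 in control to 11.8 ± 0.06 with IL-22 (mean log2 intensity ± SD, n = 3 each). Its change was 1.37 on the log2 scale (SE 0.09, 95% interval 1.15 to 1.59), a 2.58-fold rise, at an adjusted p of 0.00039 (limma). Probe ILMN_2318568 rose from 7.92 ± 0.20, close to the dim end of the arrays, to 9.24 ± 0.12. Its change was 1.32 (SE 0.10, 95% interval 1.08 to 1.55), or 2.50-fold, with an adjusted p of 0.00053 (limma). On the background-subtracted scale the rise of ILMN_2318568 was 2.10, against 1.46 for ILMN_1787879, so that their order turned.

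In the same fit probe ILMN_1775327 fell most, from 11.5 ± 0.51 in control to 9.65 ± 0.03 with IL-22. Its change was -1.87 (SE 0.21, 95% interval -2.36 to -1.38), a 3.65-fold fall, at an adjusted p of 0.0022 (limma). Probe ILMN_2311537 fell from 12.1 ± 0.46 to 10.3 ± 0.05. Its change was -1.83 (SE 0.19, 95% interval -2.28 to -1.39), or 3.56-fold, with an adjusted p of 0.0016 (limma). The order of these 2 probes turned without control 2 (-1.57 against -1.59) and without control 3 (-2.03 against -2.05). By the rule that picked these 4 probes, the 3 IL-22 values lay apart from the 3 control values in each. Both probes that fell varied more among the control arrays than among the IL-22 arrays: ILMN_1775327 stood at 11.2, 12.1 and 11.2 in the controls and between 9.62 and 9.68 with IL-22.

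**Figure D2:**
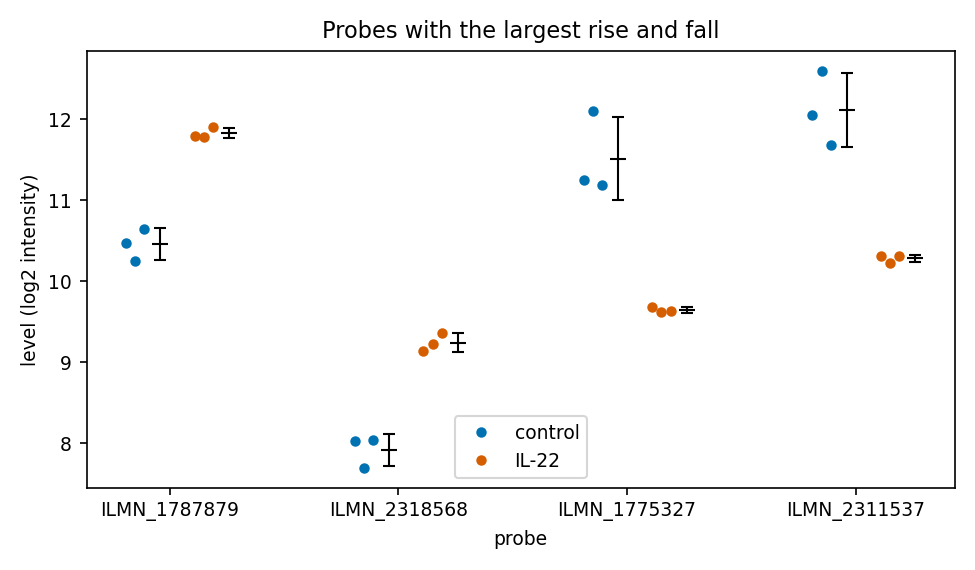
Level of the 2 probes that rose most and the 2 that fell most in the fit to all arrays (log2 intensity, y axis), with 1 coloured point per array and the mean ± SD of the 3 arrays of a group in black. The IL-22 values of ILMN_1787879 lie between 11.8 and 11.9 and its control values between 10.3 and 10.6.

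The called probes lay mainly among the brighter ones. Of the 32155 probes with a mean level under 7.5, 86 were called (0.267%), and of the 5165 probes between 7.5 and 8, 628 (12.2%). Of the 4440 probes between 8 and 9, 31.2% were called, with 724 that rose and 662 that fell. Between 9 and 10 the share was 35.3% of 2531 probes, and between 10 and 12 it was 37.9% of 2127 probes, with 454 that rose and 353 that fell. Over 12, 23.4% of 812 probes were called. In the 4 bands above 8 rises outnumbered falls among all calls in the values as deposited, but falls outnumbered rises there with cyclic loess. They also did so on the background-subtracted scale, where all calls changed at least 1.5-fold. Among changes of at least 1.5-fold, falls outnumbered rises in each of the 5 bands above 7.5 under all 3 scalings. Between 8 and 9, for example, 90 probes rose and 234 fell by that much in the values as deposited, and 62 rose and 290 fell with cyclic loess.

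**Figure D3:**
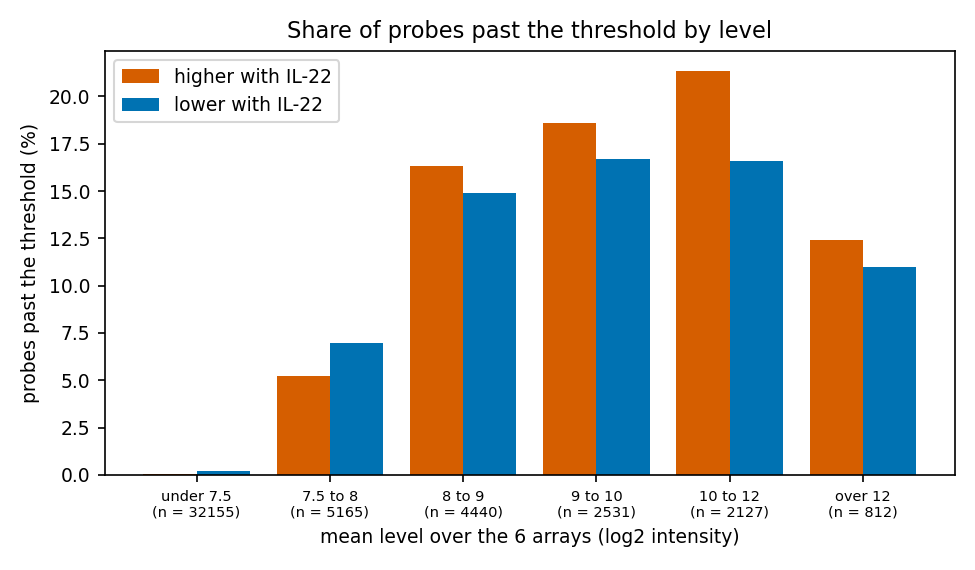
Share of probes past the threshold (%, y axis) by mean level over the 6 arrays (log2 intensity, x axis), for probes that rose and probes that fell with IL-22. The share of probes that rose went from 0.0498% under 7.5 to 21.3% between 10 and 12 and was 12.4% over 12, and it lies above the share that fell in the 4 bands over 8, an order that turned with cyclic loess.

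The 3 values of IL-22 and the 3 of control did not overlap for 10887 probes (23.1%), where chance gives 10%. When probes were called from 2 arrays of each group at 1.5-fold or more, the pair of arrays left out changed in the same direction for 88.7% to 100% of them over the 9 possible choices. With control 2 left out, the left-out pair gave a change 1.12 to 1.13 times as large (median ratio of log2 changes). With control 1 left out this ratio was 0.81 to 0.83, and with control 3 left out it was 0.47 to 0.53. The sets of probes differed: 410 to 442 were called with control 2 left out and 740 to 759 with control 1 left out. With control 3 left out, 1766 to 1827 were called.

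Control 3 stood apart from the other controls. Over the 9910 bright probes, the spread of differences was 0.19 between controls 1 and 2 and 0.13 to 0.14 between IL-22 arrays. Between control 3 and the other controls it was 0.29 to 0.33, close to the 0.32 to 0.34 between control 3 and the IL-22 arrays. Controls 1 and 2 differed from the IL-22 arrays by 0.39 to 0.43. The component that held 72.9% of the variance placed the IL-22 arrays at 0.18 to 0.20, controls 1 and 2 at -0.23 and -0.28, and control 3 at -0.07. The 6833 probes called without control 3 comprised 3486 that rose and 3347 that fell, and they included 3924 of the 3990 called with all arrays.

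**Figure D4:**
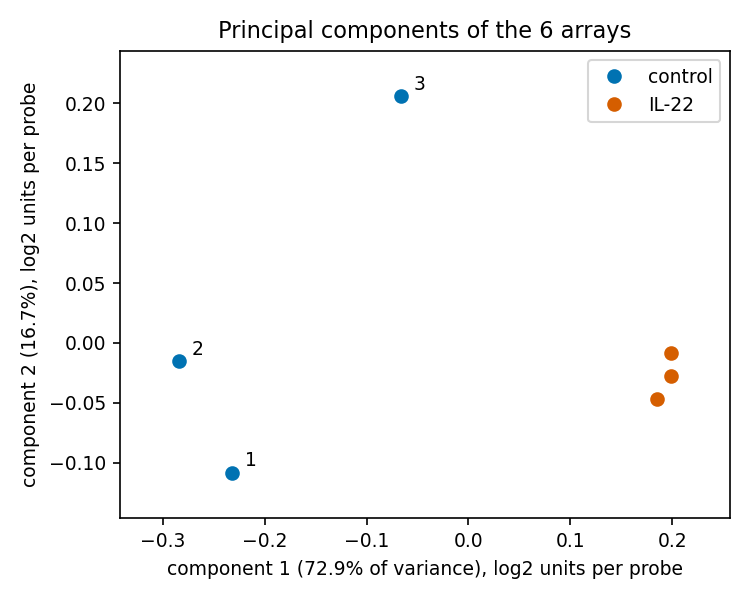
First component (72.9% of the variance, x axis) and second component (16.7%, y axis) of the 6 arrays over 9910 bright probes, in log2 units per probe, with the control arrays numbered. Control 3 lies at -0.07 on the first component, between controls 1 and 2 and the IL-22 arrays, and at 0.21 on the second, above all other arrays.

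The labels give no batch. They word the labelling step differently for the control and the IL-22 samples, and whether the groups were processed together is not given in the sources used here. Any difference in handling that followed the groups cannot be told apart from IL-22 in these 6 arrays.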

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

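The unmoderated test per probe, which was planned as a count, called 0 probes at any fold and so none of the 4 named ones. These kept their direction and their call in each of the 12 other alternatives run for them, with adjusted p (limma) of at most 0.026. Leaving out or weighting arrays could not turn their direction, since they were picked for groups that did not overlap. The changes were 1.27 to 1.46 for ILMN_1787879 and 1.21 to 2.10 for ILMN_2318568. For the probes that fell they were -2.06 to -1.57 (ILMN_1775327) and -2.05 to -1.59 (ILMN_2311537). The count of 3990 became 1680 at an adjusted p under 0.01 and 752 on the background-subtracted scale, which was chosen after the data had been examined; the cause of the latter was not tested. The unmoderated test gave 5609 probes at an unadjusted p under 0.05 against 8768 in the limma fit. Leaving out 1 array gave 1971 (without IL-22 array 3) to 6833 calls (without control 3), and 764 (without control 2) to 1768 (without control 3) of at least 1.5-fold. Cyclic loess, leaving out dim probes, trended variance and array weights kept both counts within 1.5 times of 3990 and 1127. Whether the replicate numbers pair the arrays was not settled. Deviations of same-numbered arrays from their group means correlated at 0.08, -0.05 and 0.10 over all probes. Over bright probes the values were 0.16, -0.06 and 0.19. Controls 1 and 3 correlated best with the IL-22 array of the same number, but control 2 correlated best with IL-22 array 1. With the replicate number as a block, 3938 probes were called, 3444 of them among the 3990. Not run were other offsets and normexp (planned only for a table on a linear scale), median scaling and no normalization (the arrays share 1 distribution), and 1 probe per gene and gene lists (no gene names).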

Other observations

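The tests here were chosen after the patterns they bear on had been seen, the background-subtracted scale included. Predictions were recorded as written beforehand for the comparison of control 3 between probes that rose and fell. The same holds for the share of falls after background subtraction, and the other predictions were written afterwards. A small set of probes went from dim to bright or the reverse. In 13 probes all 3 controls lay below 7.75, the 75th percentile of all values, and all 3 IL-22 arrays above 8. In 24 probes it was the other way round. No other split of the 6 arrays into 3 and 3, each of which mixes control and IL-22 arrays, gave a single such probe. With the median of 7.37 as the dim level and 7.75 as the bright level, 1 probe went from dim to bright and none the other way.

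Control 3 lay between the other controls and the IL-22 arrays. Among 1768 probes called without it at 1.5-fold or more, its median position was 0.52 on the linear scale, with controls 1 and 2 at 0 and the IL-22 arrays at 1, which argues against a wrong label on an IL-22 sample. Noise on the array has no direction and would by itself leave it near 0, but calling these probes on the other controls can shift it. It stood at 0.52 over all these probes and at 0.60 on the 1108 that fell. In calls from 2 arrays per group, the left-out pair changed 0.47 to 0.53 times as much with control 3 left out. The ratio was 0.81 to 0.83 with control 1 left out and 1.12 to 1.13 with control 2 left out. These ratios rest on unlike sets of called probes, the largest with control 3 left out, so their sizes are not directly comparable. The shift under noise alone was not tested, so noise is not excluded. If the deposited values are plain log2, a mixture of control and IL-22 RNA would place control 3 equally on probes that rose and fell. Its position was 0.32 on the 660 that rose, a difference of -0.28 (95% bootstrap interval over probes -0.32 to -0.24, with probes not independent). On the log2 scale, where a mixture would place it further along on probes that rose, its median position was 0.39 on these and 0.51 on those that fell. These positions count against a mixture at a fixed proportion only if the values are plain log2. No label states that, so a mixture stays open. The number of bright probes where it lay over 0.5 outside the range of the other arrays (75) was 2.78 times the highest of the others, between the bounds set for that test. A difference in the state or handling of that sample may be another candidate explanation, which no label bears on, and no biological explanation was tested. Control 3 still lay on the control side of all 3 IL-22 arrays for 84.4% of the probes that rose and 91.3% of those that fell.

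Falls of at least 1.5-fold outnumbered rises, with 63.0% of 1127 calls. A log scale compressed near background would understate rises from a dim start. After background subtraction 67.8% of the calls were falls. Only 752 probes were called on that scale, against 3990 as deposited. Rises that it failed to call are not counted in that share, so the share cannot decide the point. The size of the excess varied with the arrays and settings used. Without control replicate 3 the share of falls was 62.7%, without control 2 it was 60.5%, and without control 1 it was 53.2% (484 rose and 551 fell). Without IL-22 array 1, 2 or 3 it was 56.4%, 56.1% and 55.8%. With all arrays it was 56.9% at an adjusted p under 0.01 (limma) and 74.9% with cyclic loess. All these settings started from quantile-normalized values, so the part that this normalization plays in the excess was not tested. The values argue against control 3 as the source of the excess, but it nearly vanished without control 1, so a contribution of that array stays open. At mean levels of 10 to 12, 159 probes rose and 200 fell by at least 1.5-fold as deposited. Over 12, 23 rose and 43 fell. These levels lie far above the lowest values, so the counts argue against compression near background as the source of the excess there. For dimmer probes compression stays open. Unequal handling of the groups stays open too, as does the response to IL-22 itself.

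Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many calls as 3990, and the highest of the others gave 0. These 10 splits are too few for a share under 0.05.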
